A study of Arabidopsis thaliana with 2 samples.

How the data were processed

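Steady-state RNA was profiled on 2 Affymetrix arrays, 1 for wild-type Arabidopsis thaliana (ecotype Columbia) and 1 for the double knockout KO-HsfA1d/A1e. Per the labels' protocols, plants grew on MS medium in cycles of 16 h of light at 25°C and 8 h of dark at 22°C, at 100 µE m-2 s-1, and at 2 weeks of age they received 30 min at 400 µE m-2 s-1 before harvest. Total RNA was extracted with Sepasol-RNA I, and biotinylated cRNA was made from 100 ng of it with the 3'IVT Express procedure, per the labels' protocols. Each genotype has 1 array, which its label calls biological replicate 1. No untreated array was analysed here, so the values compare genotypes after high light and give no response to light.

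The deposited values are linear intensities, 1 per probe set and array, for 16541 probe sets. The software that summarized the probes, the background correction, the scaling of the arrays and any filter on probe sets are not given in the sources used here. The deposited intensities ran from 0.489 to 25226 on the wild-type array and from 0.607 to 28565 on the mutant array. They carry no detection calls, so a dim probe set could not be told from background. For arrays, precision is limited by their number, and 1 array per genotype gives no SD, no standard error and no p-value.

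Gene names came from GEO's platform annotation, which can be old, and were updated through Entrez identifiers to the TAIR10.1 gene table. Of the 16541 probe sets, 9139 had 1 gene symbol, 340 had several and 7062 had none there. The 7062 are unnamed here. For 9095 of the 9139, the Entrez identifier matched the gene table, and the other 44 kept the symbol of the annotation. The 9139 probe sets named 9063 genes. No genome build is stated for the deposited values, so no coordinates are given.

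Intensities were taken as log2(intensity + 16), and the difference is mutant minus wild type. A log2 difference understates the change of dim probe sets because of the added 16. Fold values quoted for single genes are ratios of the deposited intensities without the added 16, so they lie slightly above the log2 differences beside them. The values were used as deposited because the medians of the 2 arrays differed by 0.02 log2 units among the probe sets past the expression filter, under the limit of 0.1 set beforehand. The expression filter kept the 8271 probe sets whose mean log2 value was at or above the median, 8.44, which corresponds to an intensity of 332. Sizes were counted at 2-fold, a log2 difference of at least 1 in either direction. These counts rest on a fixed rule of size and are not test results.

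Before the data were examined, 26 lists of gene loci were fixed. They cover the targeted genes, heat shock factors, heat shock proteins and chaperones, antioxidant and high-light genes, other stress, hormone, light-harvesting and clock genes, markers of other tissues, and reference genes. A gene counted as measured where a probe set named that gene alone. Members not measured may still lie under probe sets with no name or several names here. Each measured gene was represented by its probe set with the highest mean that names that gene alone. The median difference of a list was placed among 10000 random lists of the same size, drawn from the 9063 genes and matched in 20 bins of mean log2 value. A list was called apart under percentile 2.5 or over percentile 97.5. This percentile describes these 2 arrays and does not replace replicates. In all, 18 lists had at least 1 measured gene, and 9 of them had 3 or more.

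The other 8 lists had no probe set that named a member. They are the targeted genes (HsfA1d and HsfA1e), the other heat shock factors, HSP90 and HSP100, jasmonate, morning-phased clock, vascular, flower and seed storage genes, and they are not analysed here. The planned label check on HsfA1d and HsfA1e, the value of HsfA2, and the planned RNA quality check on control probe sets were therefore not run. There were 0 control probe sets with the AFFX prefix in the table used here.

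Genes were named by a rule fixed beforehand. It takes the 12 largest differences in each direction among singly named probe sets past the filter, then up to 4 members of each list past the filter with a difference of at least 2-fold, and up to 2 members under 2-fold only of lists described as unchanged in size. HsfA1d, HsfA1e and HsfA2 were to be named first. Other genes were chosen after their values were seen. They are the list members under the expression filter and the genes so marked in the text.

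The alternatives were median centring, quantile normalization, a loess of the difference on the mean (span 0.3), pseudocounts of 1 and 64, no expression filter, a filter at percentile 75, thresholds of 1.5-fold and 3-fold, leaving out probe sets whose ID ends in _s_at or _x_at, averaging the probe sets of a gene, keeping only list members past the filter, and 50 bins for the random lists. The procedure was tested on simulated data for the mutant against wild-type comparison, with 200 of 16541 probe sets changed 4-fold and noise of the size seen in the bulk of the real differences. It recovered 94.5% of the changed probe sets, short of the 95% first required. The remaining 11 had a mean under the expression filter and recovery among those past it was 100.0%, so the requirement was lowered to 90% after this result was seen. The changed probe sets were drawn only from named probe sets past the filter in the real data. Recovery of dim probe sets and of changes smaller than 4-fold was therefore not tested. The simulated noise has 1 spread for every intensity and leaves out the larger scatter of dim probe sets. Only 1 unchanged probe set reached 2-fold, but the simulated noise was normal, with its spread set by the bulk of the differences. The real differences past the filter had an SD of 0.35 log2 units, against 0.23 estimated from their bulk. This count is therefore no false-call rate for the real arrays. Each simulated list was placed among 1000 random lists. Of 200 unchanged lists of 11 genes, 3.5% were called apart, and of 50 lists with 6 lowered genes, 100.0% were. Lists of other sizes were not simulated, so the shorter lists described below were not covered. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.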

Results

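Gene expression after high light was compared between wild-type Arabidopsis rosette leaves and leaves of the KO-HsfA1d/A1e mutant. HsfA1d and HsfA1e encode class A1 heat shock factors, transcription factors that switch on heat shock protein genes. The data consist of 1 array per genotype with 16541 probe sets each. Median intensity was 334.1 on the wild-type array and 331.9 on the mutant array, and the log2 values of the arrays correlated across probe sets with Pearson's r = 0.98. Probe sets are not independent replicates. With 1 array per genotype there is no replicate error, no test could be made, and every difference below compares these 2 arrays.

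The comparison asks which transcripts depend on the pair of heat shock factors when leaves are under high light. Transcripts of small heat shock proteins, the HSP70 gene Hsp70-2 and several co-chaperones were lower in the mutant than in the wild type, by up to 15.7-fold among those past the expression filter. Among the 8271 probe sets past the expression filter, 114 were at least 2-fold lower in the mutant and 10 were at least 2-fold higher, while 98.5% stayed within 2-fold. At 4-fold, 30 were lower and 1 was higher, and at 8-fold 7 were lower and 0 were higher. The counts depend on these settings, with 377 lower and 127 higher without the filter and 276 lower and 129 higher at 1.5-fold. The central 95% of differences lay between -0.68 and 0.52 log2 units.

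The only error estimate within these arrays came from genes measured by a pair of probe sets. For the 13 such genes past the filter, the mutant minus wild-type differences of a gene's probe sets were compared. They had an SD of 0.20 log2 units around their mean, and the largest gap between them was 0.56. This describes scatter between probe sets on the same arrays. It leaves out the spread between plants and any error of RNA preparation, labelling or hybridization that the probe sets share. Without the filter, the 73 such genes gave an SD of 0.32.

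Small heat shock proteins, chaperones that hold unfolded proteins in solution, stood furthest from the rest of the genes. Of 19 genes fixed for this group, 11 were measured, and 10 of these had the lower value in the mutant. Their median difference was -2.57 log2 units, below all 10000 random lists matched on expression (percentile 0), whose median was 0.03, and over the 8 members past the filter it was -1.81. Of the 8 members past the filter, 5 were at least 2-fold lower and 0 were at least 2-fold higher. AT1G53540, a cytosolic class I member, had an intensity of 4984 in the wild type and 317.5 in the mutant, a difference of -3.91. AT5G51440, a mitochondrial member, had 5057 against 464.9 (-3.40), and AT2G29500, also of class I, had 9873 against 965.2 (-3.33). AT5G37670, a peroxisomal member, had 5818 against 963.3 (-2.57). The remaining member at least 2-fold lower, AT2G19310, had 8907 against 4284 (-1.05) and was named after its value was seen.

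Of the members past the filter, 3 were under 2-fold, and they were named after their values were seen. AT1G54050 was among the brightest, with 14449 in the wild type and 9172 in the mutant (-0.65), and AT4G21870 had 2807 against 1927 (-0.54). AT5G54660 had the opposite sign, 397.2 against 459.3 (0.20). The other 3 of the 11 were under the filter and were named after their values were seen. ATHSP22.0 (AT4G10250), an endoplasmic reticulum member, had 909.6 in the wild type and 26.1 in the mutant (-4.46), and AT1G52560 had 662.9 against 36.5 (-3.69). Both mutant values lay close to the lowest 5% of that array, whose limit was 31.9, so the size of these differences depends on the added pseudocount. AT5G47600 had 101.7 against 85.1 (-0.22).

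**Figure D1:**
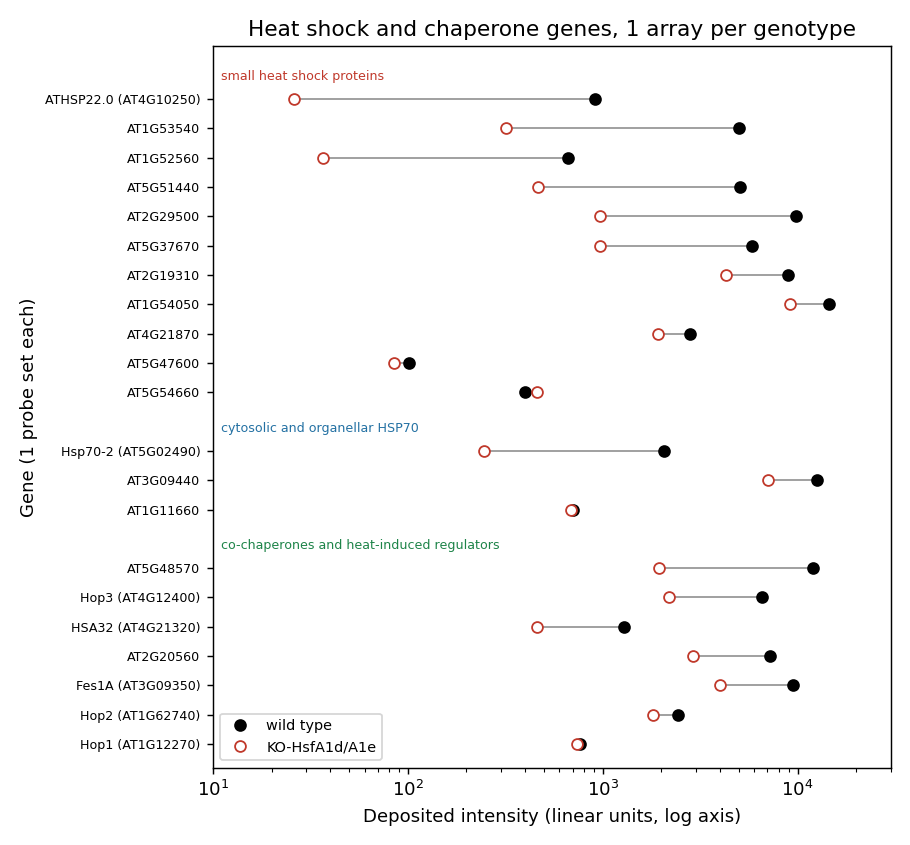
Deposited intensity (log axis) of each measured small heat shock protein, HSP70 and co-chaperone gene on the wild-type array (filled) and the KO-HsfA1d/A1e array (open), 1 probe set per gene and 1 array per genotype, with no error bars because there are no replicates. AT1G53540 lies at 4984 and 317.5, while Hop1 lies at 768.5 and 741.9.

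The measured members of the list of co-chaperones and heat-induced regulators were lower as a group as well. None of them encodes a transcription factor, so the heat-induced transcription regulators of the list were not assessed. Of 15 fixed genes, 7 were measured, all 7 past the filter and all 7 with the lower value in the mutant. Their median difference was -1.31, again below all 10000 random lists (percentile 0). At least 2-fold lower were 5 of the 7. AT5G48570, which encodes the peptidyl-prolyl isomerase ROF2, had 12073 in the wild type and 1955 in the mutant (-2.62). Hop3, a stress-induced organizing protein that links HSP70 and HSP90, had 6595 against 2177 (-1.59). HSA32, needed for long-term acquired heat tolerance, had 1284 against 458.3 (-1.45), and AT2G20560, a DnaJ-type protein, had 7245 against 2911 (-1.31). The fifth was Fes1A, an HSP70-associated factor, with 9431 against 4022 (-1.23), named after its value was seen. The related Hop2 had 2438 against 1819 (-0.42), and Hop1 had 768.5 against 741.9 (-0.05), both named after their values were seen.

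HSP70 genes were represented by only 3 of 14 fixed members. Their median difference was -0.82, at percentile 0.06 of the random lists. Hsp70-2 (AT5G02490) had 2072 in the wild type and 247.3 in the mutant (-2.99), AT3G09440 had 12548 against 7076 (-0.82), and AT1G11660 had 702.1 against 687.2 (-0.03), the last 2 named after their values were seen. HSP70 coding sequences are similar to one another, and signal from one member on the probes of another was not excluded.

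**Figure D2:**
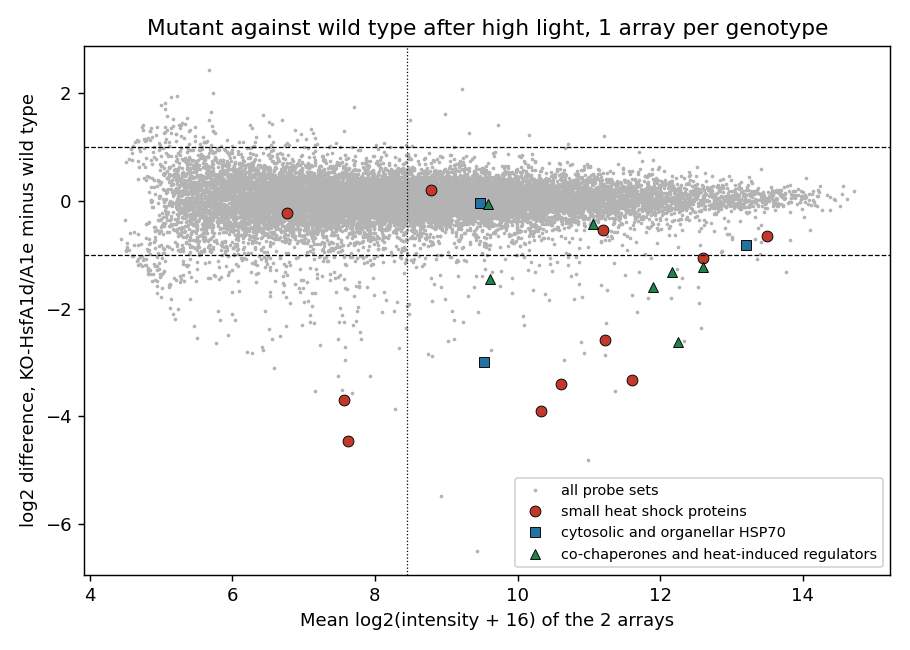
Log2 difference (KO-HsfA1d/A1e minus wild type) against the mean log2(intensity + 16) of the arrays, 1 point per probe set, with 3 gene groups coloured; dashed lines mark 2-fold and the dotted line the expression filter at 8.44. Among members past the filter, 5 of 8 small heat shock proteins and 5 of 7 co-chaperones lie below the dashed line at -1. Members under the filter are also plotted, among them ATHSP22.0 at -4.46 and AT1G52560 at -3.69.

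Beyond the chaperones, the lower transcripts included genes of other kinds. The largest difference among singly named probe sets past the expression filter was AT3G22240, with 10759 in the wild type and 366.2 in the mutant (-4.82), 29.4-fold lower. AT5G25450, a subunit of mitochondrial complex III, had 4455 against 561.7 (-2.95). AT4G19430 had 1193 against 147.2 (-2.89), AT3G60420 had 1322 against 209.5 (-2.57), AT5G52760 had 673.1 against 162.7 (-1.95), and AT3G23550 had 831.3 against 217.2 (-1.86). With AT1G53540, AT5G51440, AT2G29500, Hsp70-2, AT5G48570 and AT5G37670, these make up the 12 lowest past the filter. Of the 114 probe sets at least 2-fold lower, 53 were singly named, and the rest could not be assigned to a list. Of the 53, 11 belonged to the small heat shock protein, HSP70 and co-chaperone lists. Measured members of these lists past the filter numbered 18 of the 4173 singly named probe sets.

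Of the 10 probe sets at least 2-fold higher in the mutant, 6 were singly named. AT3G29970 had 274.8 in the wild type and 1216 in the mutant (2.08), 4.42-fold higher. SIS, known as salt induced serine rich, had 271.5 against 868.5 (1.62). AT4G33380 had 730.9 against 1723 (1.22). OSM34, the pathogenesis-related protein osmotin 34, had 1544 against 3581 (1.21), and AT4G16260, a glucanase-family gene, had 1140 against 2412 (1.07). AT2G04050, an efflux carrier of the MATE family, had 243.0 against 508.5 (1.02) and was under 2-fold after median centring. The next 6, AT3G15310, AT5G48490, AT1G75800, AT4G35720, ATRER1C1 and AT1G26920, lay between 0.83 and 0.90.

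The few measured genes of antioxidant defence did not share the lower values. All 4 measured antioxidant genes of the 18 fixed were slightly higher in the mutant, none by 2-fold. They encode glutathione reductases and chloroplast ascorbate peroxidases. The superoxide dismutases, catalases and cytosolic ascorbate peroxidases of the list were not measured. The median difference was 0.21, at percentile 92.3, inside the range of the random lists. The reference genes had a median of 0.15. GR1, a glutathione reductase, had 3851 in the wild type and 4712 in the mutant (0.29), and TAPX, the thylakoid ascorbate peroxidase, had 1269 against 1472 (0.21). Of 11 high-light and reactive oxygen responsive genes, 3 were measured, with a median of -0.62 at percentile 1.65. Of these, STZ, the zinc finger regulator Zat10, had 1414 against 917.1 (-0.62) and was the only 1 past the filter. This list's place outside the limits was lost with a pseudocount of 1 (percentile 2.71) and with 50 bins (percentile 2.77), and its median was -0.39 with a pseudocount of 64.

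The few photosynthetic genes measured differed little. Of 24 fixed light-harvesting and Rubisco-related genes, 4 were measured, all of them RCA or members of the LHCB4 family. Their median difference was 0.03, at percentile 42.1, which was -0.01 after median centring, quantile normalization and loess. RCA, Rubisco activase, had 22929 in the wild type and 25125 in the mutant (0.13, and 0.00 after quantile normalization), and LHCB4.1 had 14279 against 13945 (-0.03). By contrast, the list of the endoplasmic reticulum unfolded protein response was called apart on the lower side. Its 3 measured genes had a median of -0.37, at percentile 0.83, but none reached 2-fold. ATERDJ3B, a DnaJ protein of that compartment, had 1259 against 972.1 (-0.37), and BZIP60, a transcription factor of the response, had 1863 against 1817 (-0.04). AT4G16660, named after its value was seen, had 712.4 against 527.9 (-0.42). The 4 measured genes of the ABA, cold and dehydration list had a median of -0.06, at percentile 26.0. COR47, a dehydrin, had 3815 against 3935 (0.04), and COR15A had 384.8 against 343.8 (-0.16). The other members, COR15B (-0.53) and LTI30 (0.49), went opposite ways, were under the filter and were named after their values were seen.

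The remaining lists, apart from the reference genes, had 1 or 2 measured genes, so their percentiles describe single genes or pairs. GRX480, a glutaredoxin of salicylate signalling named after its value was seen, was under the filter with 172.7 in the wild type and 42.7 in the mutant (-1.68, percentile 0.59). WRKY53 had 443.7 against 276.7 (-0.65), and the clock gene GI had 261.9 against 197.2 (-0.38). The glucosinolate genes UGT74B1 and BCAT4 had differences of -0.43 and -0.29, the flavonoid list's HYH and DFR 0.34 and 0.31, and the auxin-responsive WES1 and GH3.3 0.25 and -0.22.

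Markers of other tissues were sparse. The root marker PYK10, a beta-glucosidase abundant in roots, had 2555 in the wild type and 3758 in the mutant (0.55), at percentile 99.0 of single genes matched on expression. The cell division marker AUR1 had a difference of 0.08 and the guard cell marker FMA one of -0.10, both under the filter. The reference genes had a median of 0.15, at percentile 80.9, with GAPC2 at 16008 against 15916 (-0.01) and PEX4, the ubiquitin-conjugating UBC21, at 1350 against 1774 (0.39). In all, 18 lists were placed among random lists, and 8 of them were called apart, 3 of these on a single gene (WRKY53, GRX480 and PYK10). WRKY53 was inside the limits with a pseudocount of 64 (percentile 3.01) and with 50 bins (percentile 3.04).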

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

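No paired analysis was possible because each genotype has only replicate 1, and leaving out a replicate was not possible for the same reason. Checks on the targeted genes and on control probe sets were not run, since no such probe set was named here. The counts at 2-fold moved by over 1.5 times only where the filter or the threshold was altered, which changes the probe sets counted by construction. For 10 higher and 114 lower, the counts became 127 and 377 with no filter on dim probe sets, 3 and 65 with the filter at percentile 75, 129 and 276 at 1.5-fold, and 2 and 51 at 3-fold. A filter on the brighter of the 2 values, chosen after seeing the data, gave 16 higher and 167 lower. The lower share of calls was 91.9%, against 74.8% with no filter and 68.1% at 1.5-fold. Of the lists, only the high-light list and the touch list (WRKY53) lost their place outside the limits. The high-light median was -0.62 with a pseudocount of 1 (percentile 2.71) and -0.62 with 50 bins (percentile 2.77), and with a pseudocount of 64 it was -0.39 but stayed outside the limits (percentile 1.27). WRKY53 was at -0.58 with a pseudocount of 64 (percentile 3.01) and -0.65 with 50 bins (percentile 3.04), and the cause was not tested. The other 135 list values kept their call, and no list called apart turned its sign. Some of these values could not change, so the count overstates how far the calls were tested. Median centring shifts every gene alike and leaves each percentile as it was. Keeping only members past the filter leaves lists wholly past it unchanged, and averaging the probe sets of a gene altered no list median. Of the lists inside the limits, the light-harvesting and Rubisco median turned from 0.03 to -0.01 after median centring, quantile normalization and loess, and the auxin median from 0.01 to -0.02 after median centring and loess. Of the 12 largest differences each way, 117 values under the scalings and pseudocounts kept their sign and side of 2-fold. The exceptions were AT2G04050 at 0.98 after median centring, 0.99 after loess and 0.90 with a pseudocount of 64. The small heat shock protein median was -1.81 over members past the filter. Dim probe sets are limited by unknown background.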

Other observations

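The counts after median centring, quantile normalization and loess and with the filter at percentile 75 were planned; their use as tests of explanations, the other tests in this part and the plastid group were chosen after the results were seen. Some single genes outside the fixed lists, picked from the 2-fold differences after their values were seen, stand for no group. Cpn60beta2, a chloroplast chaperonin subunit, had an intensity of 8537 in the wild type and 2812 in the mutant (-1.60 log2 units). Its relatives Cpn60beta3, with 582.2 against 447.8 (-0.37), and Cpn60beta4, with 631.8 against 525.6 (-0.26), were under 2-fold. SGT1A, a co-chaperone of HSP90, had 3152 against 1068 (-1.55), and AT3G12050, with an Aha1 domain found in HSP90 activators, had 8279 against 3062 (-1.43). AT5G12110, an elongation factor subunit, had 10285 against 3376 (-1.60), and AT2G41090, a calmodulin-like protein, had 8452 against 2425 (-1.79).

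Transcripts encoded in the plastid genome were taken as a group. It was picked after the data had been seen and after 34 groups of genes sought by keyword in their names had been looked at. Its 62 genes had a median difference of 0.05, at percentile 63.4 of random lists matched on expression, and 0 of the 25 past the filter reached 2-fold. Of the 37 under the filter, 2 were at least 2-fold higher, the dim rps15 (16.5 against 69.6, 1.40) and psbN (5.31 against 35.9, 1.28), and 0 were lower by as much. The differences past the filter ran from -0.45 for petA, with 396.7 in the wild type and 285.1 in the mutant, to 0.62 for ccsA, with 478.9 against 742.7. The bright atpB had 13392 against 13781 (0.04). Plastid transcripts mostly lack the long poly(A) tails that 3' labelling primes on, so their levels are less certain.

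Among probe sets past the filter, the most negative differences belong to probe sets with no gene name here. The lowest 2 had 6520 in the wild type against 56.3 in the mutant (-6.50) and 3237 against 56.7 (-5.48). The highest 2 of these unnamed probe sets had 197.6 against 590.1 (1.51) and 500.3 against 1365 (1.42).

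Lower values outnumbered higher ones in the mutant, with 114 against 10 probe sets at 2-fold. A scaling offset between the arrays is argued against by its small size. Past the filter, median centring shifted the differences by -0.03 log2 units and quantile normalization by a median of -0.004. The ratio of lower to higher counts was at least 13.0 after both, but shifts this small could hardly change it, so the ratio adds little. An intensity-dependent trend is argued against by a ratio of 15.0 after loess, and scatter of dim probe sets by a ratio of 21.7 among probe sets at or above percentile 75 of the mean. The size of the imbalance depends on brightness and threshold, with a ratio of 2.97 without the filter and 2.14 at 1.5-fold. The genotype, untested, and a difference between the plant pools or hybridizations other than genotype stay open and cannot be told apart with 1 array per genotype.

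Members of the heat shock and chaperone lists differed unequally, with 13 of 21 lower at 2-fold or more and 8 under 2-fold. Compression of bright signals is argued against as the whole cause, since 6 of the 8 had a wild-type intensity below 5818, the median of the 13. Cross-hybridization between paralogs stays open: 0 of the 8 probe sets have an ID ending in _s_at or _x_at, but probe sequences were not used here. Whether the members depend unequally on these factors was not tested. Deciding it would take 2 or more arrays per genotype, but these alone would leave cross-hybridization open. Without an untreated array, members that high light does not induce also could not be told from members independent of the factors.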
